A study of Mus musculus with 12 samples.

How the data were processed

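RNA was sequenced from mouse embryonic stem cells (ESC) that carry a doxycycline-inducible HA-Flag-AGO2 transgene, with and without doxycycline (dox). Dox was given at 2.5 ug/ml for 15 h, per the labels' protocols. RNA came either from isolated nuclei or from whole cells (total RNA), and libraries were directional and depleted of ribosomal RNA, per the labels' protocols. The labels list 12 libraries in 4 groups of 3: nuclear RNA with dox, nuclear RNA without dox, total RNA with dox and total RNA without dox. No label says whether the 3 libraries of a group came from separate cultures.

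The submitters' processing notes name bcl2fastq 2.17.1, TopHat and the mm10 build. Per the file headers, RPKM values and an ANOVA were computed in Partek 6.6; the gene annotation and the counting of reads are not stated, nor is whether the counting used strand. The deposited table holds 19716 genes, with group means over libraries on the log2 scale, log2(RPKM + 0.001), per the file headers. It also gives the authors' ANOVA p-value and q-value for dox against no dox in nuclear and in total RNA. The authors' ratio column is 2 to the power of the difference of the group means, to within 5.4e-05 on the log2 scale. The authors' signed fold change, treated here as a score, is the ratio or, below 1, minus its inverse, to within a relative 5.3e-06. Values of single libraries were not used here, so no mean printed from the authors' table has an SD.

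The spread between libraries was recovered from the deposited p-values. Each gene has 2 p-values and 2 differences of means, and with the right residual degrees of freedom both give the same residual standard deviation. With 6 degrees of freedom they did so within 0.001 on the log2 scale for 100% of 16415 genes, and with 5 or 7 for 3.16% and 4.34%. Genes above 0 in 1 group alone piled up at the t values that 1 library in 3 gives for nuclear dox (138 of 150 genes) and total no dox (727 of 947), and 1 library in 2 for nuclear no dox (351 of 399) and total dox (136 of 143). The ANOVA was therefore read as a fit of 10 libraries with group as its single factor, with 3, 2, 2 and 3 libraries in nuclear dox, nuclear no dox, total dox and total no dox. Which 2 of the 12 listed libraries stayed out is unknown. The smallest steps of low RPKM values gave the depth of the 10 libraries. Nuclear dox had 10.3, 10.9 and 11.2 M reads, nuclear no dox 15.6 and 18.9, total dox 10.96 and 11.8, and total no dox 15.3, 15.9 and 16.9.

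Because the table holds means, the tests planned before the data were examined (for counts, or for values of single libraries) were replaced. limma 3.58.1 in R 4.3.3 took the group means and the recovered residual standard deviations, moderated the variances along a trend on mean expression (median prior degrees of freedom 7.00), and tested 5 contrasts. These were dox against no dox in nuclear RNA, the same in total RNA, the difference of these effects, and nuclear against total RNA without and with dox. Tested genes had a mean of at least 1 RPKM in at least 1 group (10197 genes). P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p below 0.05. Group means in RPKM are the deposited log2 means taken back to the RPKM scale, less 0.001. They are thus geometric means, in which a library without reads counts as 0.001 and pulls the mean far down. Fold changes are on the log2(RPKM + 0.001) scale as deposited. Where only some libraries of a group hold reads of a gene, the small pseudocount stretches its fold. No fold is given against a group listed at 0.

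The procedure was tested on simulated data: 10169 genes, 3, 2, 2 and 3 libraries, and 200 genes changed in nuclear RNA. It returned the residual standard deviation of 100% of genes within 1%, called 64% of genes changed by 1 on the log2 scale and 94% of those changed by 2, and 3.66% of its nuclear calls were unchanged genes. In simulated total RNA, where nothing changed, it made 0 calls. Of 132 simulated calls of the difference of the effects 10 were unchanged genes. The noise was drawn independent and normal from the model that was then fitted, so the return of the standard deviations was fixed by construction. Genes with reads in only some libraries and correlation between genes were not simulated.

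Gene lists (25) were fixed before the data were examined. They cover nuclear-retained long noncoding RNAs, genes with detained introns, mitochondrially encoded mRNAs (0 members in the table), mRNAs of ribosomal proteins, of the respiratory chain, of replication-dependent histones and of proteins made at the endoplasmic reticulum (ER), snoRNA host genes, pluripotency genes of the naive and of the primed and formative state, markers of neuroectoderm, mesoderm, endoderm, trophectoderm, 2-cell-like cells and fibroblast feeder cells, the small RNA silencing machinery, deadenylation and mRNA decay, reported targets of miR-290/miR-302 and of let-7, ATF4 and amino acid stress genes, p53 targets, interferon-stimulated genes, immediate early genes, and heat shock genes and chaperones. Lists with at least 5 tested members were compared with all other tested genes by limma's camera (two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg within a comparison). An inter-gene correlation cannot be estimated from group means, so each test was repeated with 0.05.

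Genes were matched by symbol to GENCODE vM21 (mm10) for exon length, GC content and 3' UTRs. An exon length was found for 98.5% of the genes, and 250 genes matched through an older symbol. Genes whose longest annotated 3' UTR holds a match to positions 2 to 8 of a miRNA were tested for 14 miRNA families, of which 5 are not expected in ESC. Each set was tested by camera and against 10000 random sets matched on 3' UTR length and expression but not on GC content, with a two-sided p.

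Genes are named in the text by a rule written before the data were examined: the 10 largest changes each way in a comparison (5 for the difference of effects), and up to 4 called members of each list. Predicted genes were left out, and the higher group had to average at least 1 RPKM. The rule also asked that the libraries of the groups not overlap, which cannot be checked on means. Exceptions are marked in the text. Alternatives varied the scaling, the filter, the RNAs of large share, the fold threshold, the moderation, and trends on exon length and GC content. Genes of near-identical families, such as histone and ribosomal protein genes with their processed pseudogenes, can share reads, and overlapping or antisense genes too, so single members are uncertain.

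Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.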

Results

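RNA levels were measured by sequencing in nuclei and in whole mouse ESC, with or without 15 h of dox to induce HA-Flag-AGO2, the Argonaute protein that carries miRNAs and small interfering RNAs. The labels list 12 libraries, 3 in each of 4 groups, and the deposited group means rest on 10 of them. Nuclear RNA with dox had 3 libraries of 10.3 to 11.2 M reads and total RNA with dox had 2 of 10.96 and 11.8 M reads. Nuclear RNA without dox had 2 libraries of 15.6 and 18.9 M reads and total RNA without dox had 3 of 15.3 to 16.9 M reads. Every dox library was thus shallower than every library without dox.

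Ago2, the induced gene, was lower in the columns labelled dox. In the authors' deposited table the endogenous locus (ENSMUSG00000036698.11, mm10 chromosome 15, 73095844 to 73184935, minus strand) averaged 2.39 RPKM in dox-labelled and 8.65 RPKM in no-dox nuclear RNA, and 3.43 against 9.12 RPKM in total RNA. The fall was 3.61-fold in nuclear RNA (log2 -1.85, SE 0.166, limma Benjamini-Hochberg adjusted p = 4.94e-07) and 2.66-fold in total RNA (log2 -1.41, SE 0.166, adjusted p = 7.91e-06). The columns labelled nuclear did not differ from total in Ago2 without dox (log2 -0.08, adjusted p = 0.746). With dox Ago2 was 1.43-fold lower in the nuclear columns (limma adjusted p = 0.0239), a call that ended under 5 alternative settings. Nothing in the labels says how much of the transgene is counted at this locus. Since Ago2 goes against the dox label, groups are named below only as the columns are labelled, and each direction holds for those columns.

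The comparison of dox with no dox in nuclear RNA asks what induced AGO2 changes among RNAs in the nucleus. Messenger RNAs of histones, ribosomal proteins and the respiratory chain were higher in the dox-labelled nuclear columns, and long noncoding RNAs that stay in the nucleus were lower. Of 66 tested replication-dependent histone genes 64 were higher and 0 lower, with a median log2 fold change of 3.25. Hist1h4n rose 14.0-fold and Hist1h2ab 12.99-fold. Of 20 nuclear-retained long noncoding RNAs 19 were lower and 0 higher, with a median of -2.55: Xist, which silences an X chromosome, fell 12.9-fold, and Kcnq1ot1, the antisense RNA of an imprinted domain, fell 10.01-fold. In all, 4394 of 10197 genes were higher and 2679 lower at a limma Benjamini-Hochberg adjusted p below 0.05, 2614 and 1597 of them at least 2-fold.

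Ribosomal protein genes were higher for 79 of 84 members (2 lower, median 1.87), among them Rpsa (6.74-fold) and Rpl8 (6.49-fold). Respiratory chain genes encoded in the nucleus were higher for 67 of 78 (1 lower, median 1.24), led by Uqcrc1, a core subunit of complex III (5.68-fold). Amino acid stress genes under ATF4 were higher for 30 of 37 (2 lower, median 1.15): Phgdh, which opens serine synthesis, rose 4.63-fold and Asns, asparagine synthetase, 3.88-fold. Heat shock and chaperone genes were higher for 17 of 20 (1 lower, median 1.18), with Hspb1 up 5.90-fold and Fkbp4 up 4.75-fold. Quantile normalization turned the direction of this list relative to other genes (median -0.03, adjusted p = 0.963). The RNase P RNA Rpph1 rose 19.8-fold, from 1620 to 32200 RPKM in the authors' deposited table.

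Genes with detained introns were lower for 17 of 29 members (4 higher, median -0.39); Clk1, a kinase of splicing factors, fell 6.64-fold and Pnisr 6.25-fold. Of 18 snoRNA host genes 13 were lower and 1 higher (median -0.82), with Gas5 down 2.91-fold and Snhg14 down 4.73-fold. Among 50 genes of secreted and membrane proteins made at the ER 36 were lower and 6 higher (median -0.77), such as Tfrc, the transferrin receptor (3.24-fold), and Lrp6, a Wnt co-receptor (3.03-fold). The miRNA host transcript Mir17hg, a member of the long noncoding list, fell 8.64-fold. Mir1188, a miRNA gene within an intron of Rian, averaged 0.0104 RPKM in the dox-labelled nuclear columns and 3.40 RPKM in the no-dox nuclear columns in the authors' deposited table (limma adjusted p = 0.012, SE 2.57 on the log2 scale), a call that ended without moderation (adjusted p = 0.0643).

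Pluripotency genes went both ways. Of 39 naive pluripotency genes 20 were higher and 7 lower in dox-labelled nuclear RNA. Pou5f1 (Oct4) rose 5.16-fold (log2 2.37, SE 0.113, adjusted p = 2.71e-09) and Utf1 4.46-fold, while Rif1 and Tet2 each fell 4.20-fold. The list did not stand apart from other genes (camera adjusted p = 0.268), but the result depended on the setting: with no low-value filter it lay above other genes (adjusted p = 0.00457) and with quantile normalization below them (median -0.51, adjusted p = 9.72e-05). Of 26 genes of the small RNA silencing machinery 10 were higher and 10 lower (adjusted p = 0.319), with Ago3 down 4.97-fold. Of 26 reported miR-290/miR-302 targets 9 were higher and 7 lower (adjusted p = 0.513): Dazap2 rose 3.77-fold and the BMP receptor gene Bmpr2 fell 5.92-fold. Reported let-7 targets were higher for 14 and lower for 5 of 24 (adjusted p = 0.693), with Lin28b down 3.36-fold.

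Of 25 p53 targets 12 were higher and 8 lower (camera adjusted p = 0.906), with Bax up 3.50-fold. Immediate early genes were higher for 14 of 20 and lower for 0 (adjusted p = 0.268), and interferon-stimulated genes were higher for 6 and lower for 2 of 20 (adjusted p = 0.803). Deadenylation and decay genes were higher for 17 and lower for 10 of 38 (adjusted p = 0.524). Primed and formative genes were higher for 6 and lower for 1 of 11 (adjusted p = 0.579). Of markers of other cells, endoderm genes were higher for 4 of 5 (adjusted p = 0.029; 0.0457 at an inter-gene correlation of 0.05), with Krt8 up 3.96-fold, and trophectoderm genes for 5 of 7 (adjusted p = 0.513). The table held few tested genes of the other marker lists: of 4 fibroblast feeder genes 2 were lower, of 3 genes of 2-cell-like cells 1 was lower, of 3 neuroectoderm genes 1 was higher and 1 lower, and of 2 mesoderm genes 0 were called.

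Over the lists tested in nuclear RNA 10 stood apart from other genes by camera. Those were histones (adjusted p = 3.67e-81), ribosomal proteins (2.45e-33), long noncoding RNAs (1.15e-14), the respiratory chain (3.12e-10), ER proteins (2.4e-07), detained introns (5.47e-06), ATF4 (1.38e-05), heat shock (5.14e-05), snoRNA hosts (6.59e-04) and endoderm genes. All 10 also passed at a correlation of 0.05, where the camera adjusted p of the histones was 3.16e-32. These p-values weigh genes against other genes and do not measure the spread between cultures. Adjusted over the list alone, the counts were the same for histones (64 higher) and long noncoding RNAs (19 lower), and differed by at most 2 genes in the other lists. The median of all genes was log2 0.28, so list medians relative to all genes were 2.96 for histones, 1.59 for ribosomal proteins and -2.83 for long noncoding RNAs. With quantile normalization 54.1% of calls were higher in place of 62.1%, the ribosomal protein median fell to 0.08 (30 higher, 15 lower), and the ribosomal, respiratory, ATF4 and endoderm lists no longer passed (adjusted p = 0.482, 0.0586, 0.0917 and 0.255). With means centred on the median of tested genes 56.0% of calls were higher, and with a trend on exon length removed 52.96%.

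The size of the change followed the length of the transcript. In nuclear RNA the median log2 fold change fell from 0.98 in the tenth of genes with the shortest exons to -0.83 in that with the longest, and in total RNA from 0.66 to -0.60. Across 10122 genes, which are not independent replicates, Spearman's rho with exon length was -0.418 in nuclear and -0.345 in total RNA, and with GC content 0.468 and 0.434. After both trends were removed 3084 genes were called higher and 2748 lower in nuclear RNA, of which 2603 and 1736 had been called in that direction before. The detained intron list was no longer apart (median -0.02, adjusted p = 0.427), nor were the endoderm genes (0.79, adjusted p = 0.702).

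**Figure D1:**
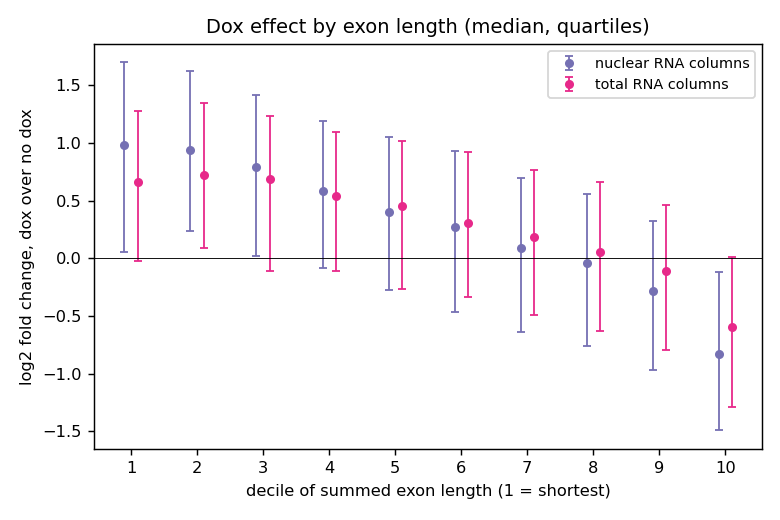
Log2 fold change of dox-labelled over no-dox columns by decile of summed exon length, as medians (points) with quartiles (bars), for nuclear and total RNA columns. Medians ran from 0.98 to -0.83 in nuclear and from 0.66 to -0.60 in total RNA.

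In total RNA the same comparison asks what induced AGO2 changes in whole cells. Histone genes, and with them mRNAs of ribosomal proteins and the respiratory chain, were again higher in the dox-labelled columns, and nuclear-retained RNAs lower. Histone genes were higher for 65 of 66 (0 lower, median 2.52), with Hist2h4 up 7.93-fold and Hist1h1a up 7.48-fold. Nuclear-retained long noncoding RNAs were lower for 18 of 20 (0 higher, median -2.06), with Kcnq1ot1 down 8.36-fold and Xist 8.06-fold. Across the transcriptome 4233 genes were higher and 2323 lower by limma at a Benjamini-Hochberg adjusted p below 0.05, 2286 and 1291 of them at least 2-fold, and the median of all genes was log2 0.26.

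Ribosomal protein genes were higher for 77 of 84 (1 lower, median 1.28, camera adjusted p = 7.1e-21), such as Rpsa (5.36-fold), and respiratory chain genes for 58 of 78 (2 lower, median 0.76, adjusted p = 1.12e-05; 0.112 at 5 RPKM and 0.198 with the length trend removed, at a median of 0.21), such as Uqcrc1 (4.18-fold). ATF4 genes were higher for 27 of 37 (2 lower, adjusted p = 5.64e-06), with the serine enzyme Psat1 up 4.27-fold, and heat shock genes for 18 of 20 (1 lower, adjusted p = 3.25e-06), with Hspb1 up 4.54-fold. Lower were 37 of 50 ER protein genes (1 higher, adjusted p = 2.09e-11), among them Itgav (3.07-fold) and Lrp6 (3.00-fold), 12 of 18 snoRNA host genes (2 higher, adjusted p = 8.22e-03), with Snhg14 down 4.63-fold, and 13 of 29 genes with detained introns (7 higher, adjusted p = 1.02e-03), with Pnisr down 5.08-fold and Clk1 3.84-fold. The detained intron call ended when the length and GC trends were removed (adjusted p = 0.959). Rpph1, the RNA gene of RNase P, and the related Rprl3 rose 21.4-fold and 15.9-fold.

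Pou5f1 rose 3.98-fold in dox-labelled total RNA, while Rif1 fell 3.85-fold and Tet1 3.39-fold. Naive pluripotency genes were higher for 23 and lower for 9 of 39 (camera adjusted p = 0.139); the list lay above other genes with no low-value filter (adjusted p = 0.000858) and below them with quantile normalization (median -0.19, adjusted p = 0.0295). Immediate early genes were higher for 14 of 20 and lower for 0 (adjusted p = 0.0319; adjusted p = 0.119 at a correlation of 0.05), with Jund up 3.15-fold and Myc up 3.19-fold. Of 26 reported miR-290/miR-302 targets 11 were higher and 4 lower (adjusted p = 0.908), with Cdkn1a up 2.92-fold and Bmpr2 down 7.35-fold. Let-7 targets were higher for 14 and lower for 4 of 24 (adjusted p = 0.533). Silencing machinery genes were higher for 10 and lower for 9 of 26 (adjusted p = 0.623), and Ago3 fell 5.38-fold. Of 25 p53 targets 11 were higher and 9 lower (adjusted p = 0.908). Interferon-stimulated genes were higher for 10 and lower for 3 of 20 (adjusted p = 0.908), decay genes higher for 17 and lower for 10 of 38 (adjusted p = 0.908), and primed and formative genes higher for 6 and lower for 1 of 11 (adjusted p = 0.623).

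Endoderm genes were higher for 3 of 5 in dox-labelled total RNA (camera adjusted p = 0.136), with Krt8 up 3.32-fold, and trophectoderm genes for 6 of 7 (adjusted p = 0.266). Of 4 fibroblast feeder genes 2 were lower. Of 3 neuroectoderm genes 1 was higher and 1 lower, and 0 of 3 genes of 2-cell-like cells and 0 of 2 mesoderm genes were called. Arhgdib rose 7.33-fold. Adjusted over the list alone, counts differed by at most 1 gene in any list. Of calls in total RNA 64.6% were higher, against 55.3% with quantile normalization and 55.0% with means centred on the median. With quantile normalization the ribosomal (median 0.03, adjusted p = 0.821), respiratory (0.07, 0.553) and heat shock lists (0.17, 0.357) no longer passed.

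The nuclear and total effects of dox were close to each other. Of the genes higher in nuclear RNA 3781 were also higher in total RNA, where independent lists would share 1824, and 2030 were lower in both, where independent lists would share 610. Opposite calls were made for 3 and 4 genes. Pearson's r of the log2 fold changes across the 10197 genes was 0.856 (0.526 with no low-value filter) and Spearman's rho 0.926. The comparisons share no library, and genes are not independent replicates. Both tests used the same residual standard deviation of a gene, pooled over the 4 groups, so their calls are not independent. When the difference of the effects was tested gene by gene, limma called 0 genes, with 1338 at an unadjusted p below 0.05. Among highly expressed members of the lists, Hist1h2ai differed by 0.69 in log2 (SE 0.145), below its list's median of 0.78, and Apoe by 0.65 (SE 0.139), each at an adjusted p of 0.0777. The median SE of this difference was 0.263. The number of calls was 0 with the length or length and GC trend removed and up to 109 higher and 12 lower when genes of at least 5 RPKM were tested. Tested as sets, 8 lists differed between fractions: histone, ribosomal, respiratory and endoderm genes rose more in the nuclear columns, and long noncoding RNAs, detained introns, snoRNA hosts and miR-290/miR-302 targets leaned lower there. The endoderm difference rests on 5 genes and ended at 5 RPKM (adjusted p = 0.0652) and with the length (0.186) or length and GC trend removed (median -0.01, adjusted p = 0.41), and the ribosomal and miR-290/miR-302 target differences ended with quantile normalization (0.124 and 0.335). Adjusted over the list alone, 54 of 66 histone, 61 of 84 ribosomal and 13 of 78 respiratory genes had a larger effect in the nuclear columns.

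**Figure D2:**
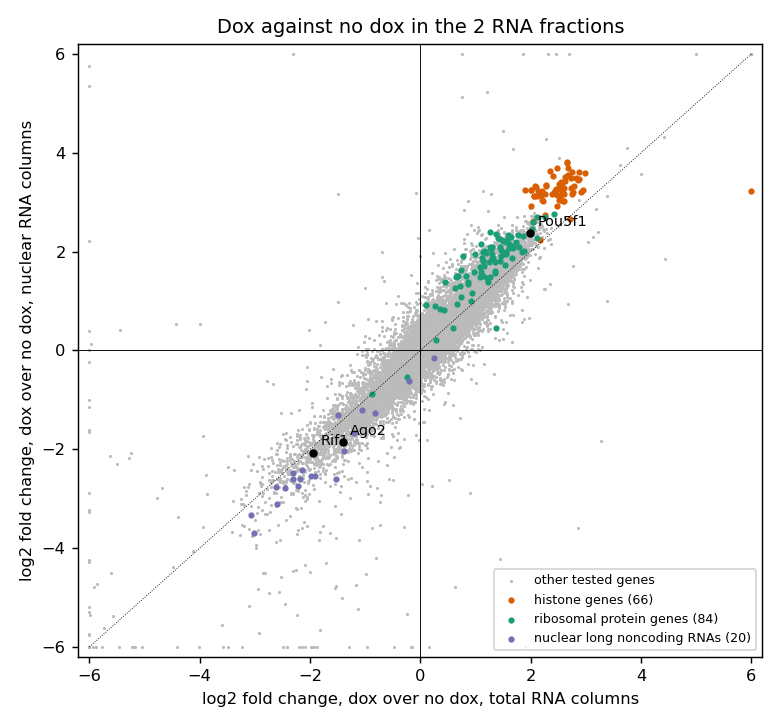
Log2 fold change of dox-labelled over no-dox columns for each tested gene, total RNA on the x axis and nuclear RNA on the y axis, with values beyond 6 drawn at 6. Histone (66) and ribosomal protein genes (84) lie mostly up and right and nuclear long noncoding RNAs (20) down and left; with quantile normalization the ribosomal medians shrink to 0.08 and 0.03.

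AGO2 acts through pairing of miRNA seeds, so genes with seed matches in their 3' UTRs were compared with other genes. In nuclear RNA the 1653 genes with a miR-290/miR-302 site, the main ESC miRNA family, had a median log2 fold change of -0.23, which is 0.108 below random sets matched on 3' UTR length and expression (log2 -0.11; permutation p = 0.0004, adjusted p = 8e-04). In total RNA the shift was -0.03 (permutation p = 0.095). Site genes of miR-26 (-0.18, adjusted permutation p = 0.0014), miR-21 (-0.13, 0.0028), miR-25/miR-92 (-0.10, 0.0358) and miR-130/miR-301 (-0.08, 0.0358) were shifted down there. Those of miR-15/miR-16 were shifted up (0.085, adjusted permutation p = 0.0014). By camera genes of 13 of 14 families lay below other genes in nuclear RNA and 13 in total RNA, including 4 of the 5 families not expected in ESC. In nuclear RNA the shift from matched sets was larger for miR-26 (-0.22), miR-21 (-0.22), miR-25/miR-92 (-0.19), miR-130/miR-301 (-0.13) and miR-17/miR-20/miR-106 (-0.13). It went up for let-7 (0.12) and miR-15/miR-16 (0.07). Of the 5 families not expected in ESC 2 moved about as far as miR-290/miR-302 but upward, miR-133 (0.11, adjusted permutation p = 0.00529) and miR-122 (0.10, adjusted permutation p = 0.0235). The other 3 moved less: miR-1/miR-206 (-0.05, adjusted permutation p = 0.121), miR-124 (0.03, 0.206) and miR-9 (-0.03, 0.393). At an inter-gene correlation of 0.05 genes of 0 families passed (miR-290/miR-302 adjusted p = 0.0678 in nuclear and 0.149 in total RNA). The random sets were not matched on GC content, with which the dox effect rose (Spearman's rho 0.468 in nuclear RNA). With the length and GC trends removed, genes with an 8-mer site (the match followed by an A) were compared with all genes with a 3' UTR. In nuclear RNA they lay at -0.19 for miR-290/miR-302 and -0.22 for miR-124, a family not expected in ESC.

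Nuclear was then compared with total RNA without dox, which asks what RNAs nuclei hold more or less of than whole cells. Lin28a, an RNA-binding protein gene of early embryonic cells that blocks let-7 maturation, was 22.5-fold higher in the columns labelled nuclear (log2 4.49, SE 0.177, limma Benjamini-Hochberg adjusted p = 6.12e-09). Lefty1, a Nodal inhibitor gene, was 6.42-fold lower, and interferon-stimulated and p53 target genes were lower there as lists. Long noncoding RNAs known to stay in nuclei lay close to other genes: 3 of 20 were higher and 2 lower, with a median log2 of -0.01, which is 0.30 above the median of all genes (camera adjusted p = 3.07e-03; 0.0295 at a correlation of 0.05). Malat1, a hallmark nuclear RNA, was 1.36-fold lower in the nuclear columns (log2 -0.44, SE 0.128, adjusted p = 0.0154), a call that ended under quantile normalization (adjusted p = 0.178), with centred means (0.539), with no low-value filter (0.0649) and without moderation (0.0602). Of all genes 409 were higher and 3539 lower, 154 and 1150 of them at least 2-fold, about a median of log2 -0.31. The split depends on that shift: 10.4% of calls were higher as deposited, 50.7% with quantile normalization, 42.4% with centred means and 44.5% with the length trend removed. Counts of list members below are on the deposited scale unless a sentence says otherwise, while camera compares a list with other genes.

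Further genes higher in the nuclear columns were Rasgrp2 (13.6-fold), Kis2 (9.70-fold), Efs (9.68-fold) and Gbx2, a homeobox gene of naive pluripotency (5.29-fold). Among long noncoding RNAs Firre rose 1.86-fold and Mirg 1.68-fold. Of 18 snoRNA hosts 9 were higher and 0 lower (camera adjusted p = 1.63e-06), with Epb41l4aos up 1.78-fold, and of 37 ATF4 genes 12 were higher and 3 lower (adjusted p = 3.85e-08), with Chac1 up 4.84-fold and Phgdh up 2.25-fold. Lists that lay above other genes by camera but not at a correlation of 0.05 were detained introns (0 higher, 0 lower of 29; adjusted p = 0.0412, then 0.163), histones (9 higher, 12 lower of 66; 0.0205, then 0.163), let-7 targets (2 higher, 6 lower of 24; 8.04e-03, then 0.0625) and the silencing machinery (1 higher, 4 lower of 26; 0.0412, then 0.16). In the last list Lin28a was higher and Mov10, an Argonaute-associated helicase gene, was 2.47-fold lower.

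Lower in the nuclear columns without dox were 14 of 20 interferon-stimulated genes (0 higher, median -1.48, or -1.17 relative to all genes; camera adjusted p = 9.52e-06; at 5 RPKM median -0.62, adjusted p = 0.104), with the peptide transporter gene Tap1 down 19.3-fold. Of 25 p53 targets 17 were lower and 1 higher (adjusted p = 1.5e-03): Cdkn1a, the p21 cell cycle inhibitor gene, fell 3.37-fold, Btg2 3.90-fold and Ei24 3.68-fold. Of 26 reported miR-290/miR-302 targets 18 were lower and 1 higher (median -0.62, or -0.31 relative to all genes; adjusted p = 3.35e-05), with Lefty1, Dazap2 (3.90-fold) and Ei24 as the largest. With centred means 7 of these were lower and 2 higher. ER protein genes were lower for 43 of 50 (3 higher, adjusted p = 6.32e-12), such as Col4a1 (3.61-fold) and Itgav (3.58-fold). Ribosomal protein genes were lower for 74 of 84 (0 higher, adjusted p = 9.05e-08), with Rps29 down 2.23-fold, respiratory genes for 57 of 78 (0 higher, adjusted p = 1.5e-03; 0.0717 at 0.05), with Ndufa3 down 2.24-fold, and heat shock genes for 14 of 20 (0 higher, adjusted p = 0.0184; 0.0784 at 0.05). Much of these counts is the shift of all genes: with centred means 11 interferon-stimulated (0 higher), 8 p53 target (1 higher), 31 ER protein (6 higher), 30 ribosomal (0 higher), 17 respiratory (0 higher) and 4 heat shock genes (0 higher) were lower, and the heat shock list no longer passed (adjusted p = 0.162).

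Among markers of other cells the endoderm list had 4 of 5 genes lower and 1 higher (camera adjusted p = 3.15e-07), with the keratins Krt19 down 11.7-fold and Krt8 down 6.32-fold. Of 7 trophectoderm genes 5 were lower (adjusted p = 0.253). All 4 tested fibroblast feeder genes were lower, with Thbs1 down 9.68-fold, as were 2 of 2 mesoderm, 2 of 3 neuroectoderm and 1 of 3 2-cell-like genes. Adjusted over the list alone, counts in this comparison differed by at most 3 genes, for the respiratory (60 lower) and decay lists (5 lower). Anxa3 and Anxa1 fell 30.01-fold and 26.9-fold, and Ido2 fell 57.7-fold, from 1.64 to 0.0274 RPKM in the authors' deposited table. Lists that did not stand apart were naive pluripotency (5 higher, 16 lower of 39; adjusted p = 0.9, upward with quantile normalization at a median of 0.32 and an adjusted p of 0.0488), primed and formative (1 higher, 4 lower of 11; 0.934), immediate early (2 higher, 11 lower of 20; 0.253) and decay genes (1 higher, 8 lower of 38; 0.934). Lefty2, a naive pluripotency list member, fell 3.42-fold. Genes of 0 miRNA families lay apart by camera, but miR-290/miR-302 site genes lay below matched sets by a small margin (-0.04, permutation p = 0.0012, adjusted p = 8.4e-03). So did site genes of miR-17/miR-20/miR-106 (-0.05, adjusted permutation p = 0.0028) and miR-25/miR-92 (-0.06, adjusted permutation p = 0.0168).

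The comparison of nuclear with total RNA was repeated in the columns labelled dox. There too, the pluripotency factor Lin28a stood far apart. Lin28a was 36.3-fold higher in the nuclear columns (log2 5.18, SE 0.177, limma Benjamini-Hochberg adjusted p = 2.09e-09), Gbx2 15.8-fold higher, Lefty1 6.001-fold lower and Lefty2 2.93-fold lower. Reported miR-290/miR-302 targets were lower for 19 of 26 (0 higher, median -0.86, or -0.54 relative to all genes; camera adjusted p = 4.41e-10): Lats2, a Hippo kinase gene, fell 6.69-fold and Cdkn1a 3.98-fold. Histone genes were higher for 47 of 66 (0 lower, median 0.59, adjusted p = 5.23e-32), with Hist1h2bh up 2.93-fold and Hist2h2bb up 2.42-fold. In all, 596 genes were higher and 3549 lower, 215 and 1190 at least 2-fold, about a median of log2 -0.32. As before the split followed the scaling, with 14.4% of calls higher as deposited, 45.7% with quantile normalization, 54.8% with centred means and 49.2% with the length trend removed.

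Interferon-stimulated genes were lower for 17 of 20 (0 higher, median -1.70, camera adjusted p = 1.05e-07), with the nucleic acid sensor gene Zbp1 down 14.6-fold. Of 25 p53 targets 15 were lower (0 higher, adjusted p = 2.28e-03), with Btg2 down 4.36-fold, and of 50 ER protein genes 40 were lower and 4 higher (adjusted p = 8.33e-09), with Col4a1 down 4.50-fold. ATF4 genes were higher for 15 of 37 (3 lower, adjusted p = 1.34e-10), among them Chac1 (3.53-fold), Trib3 (2.63-fold) and Phgdh (2.55-fold). Nuclear-retained long noncoding RNAs were higher for 0 and lower for 5 of 20 (adjusted p = 0.794): Malat1 fell 1.81-fold and Neat1, the scaffold of paraspeckles, 1.63-fold. With centred means 16 interferon-stimulated (0 higher), 10 p53 target (4 higher), 23 ER protein (5 higher) and 13 miR-290/miR-302 target genes (1 higher) were lower, and of the long noncoding RNAs 4 were higher and 3 lower. The Neat1 call ended under quantile normalization (adjusted p = 0.147) and with centred means (0.0778). Mov10 was 2.20-fold lower, in a silencing machinery list with 1 gene higher and 10 lower (adjusted p = 0.461).

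Endoderm genes were lower for 3 and higher for 1 of 5 (camera adjusted p = 1.36e-03; with no low-value filter median 0.04, adjusted p = 0.38), with Krt19 down 7.11-fold and Krt8 5.30-fold, trophectoderm genes lower for 6 of 7 (adjusted p = 0.0897) and fibroblast feeder genes for 4 of 4, with Thbs1 down 9.05-fold. Both mesoderm genes, 2 of 3 genes of 2-cell-like cells and 2 of 3 neuroectoderm genes (1 higher) were lower too. Anxa1 fell 26.3-fold and Ido2 50.3-fold. Adjusted over the list alone, 54 histone genes were higher and 6 respiratory and 2 ribosomal genes lower, and counts of the other lists differed by at most 3. Lists called by camera but not at a correlation of 0.05 were the ribosomal (0 higher, 5 lower of 84; adjusted p = 0.0399, then 0.264), heat shock (0 higher, 14 lower of 20; 0.0183, then 0.0835), immediate early (1 higher, 11 lower of 20; 0.0152, then 0.0769), let-7 target (3 higher, 6 lower of 24; 0.0403, then 0.155) and snoRNA host lists (3 higher, 2 lower of 18; 0.0139, then 0.0684). The ribosomal list lay above other genes as deposited and below them with quantile normalization, at a median of -0.08 in both. Lists that did not stand apart were respiratory genes (0 higher, 11 lower of 78; 0.0897), detained introns (0 higher, 16 lower of 29; 0.186), decay genes (1 higher, 17 lower of 38; 0.15), naive pluripotency (6 higher, 17 lower of 39; 0.748) and primed and formative genes (0 higher, 4 lower of 11; 0.794).

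Genes with miRNA sites were lower in the nuclear columns with dox for 5 of 14 families by camera, miR-290/miR-302 (adjusted p = 0.0112), miR-17/miR-20/miR-106 (2.5e-03), miR-25/miR-92 (0.0117), miR-130/miR-301 (0.0117) and miR-19 (0.0374). None passed at a correlation of 0.05 (adjusted p = 0.595 for each). Against sets matched on 3' UTR length and expression miR-290/miR-302 site genes were shifted by -0.07 and miR-17/miR-20/miR-106 site genes by -0.10, each at a permutation p = 0.0002, the smallest that 10000 random sets give. Site genes of miR-25/miR-92 (-0.08), miR-130/miR-301 (-0.07), miR-19 (-0.07), miR-21 (-0.06) and miR-26 (-0.04) were shifted down too, at adjusted permutation p of at most 0.0106. Those of miR-15/miR-16 were shifted up (0.03, adjusted permutation p = 0.002). Genes with sites of miR-1/miR-206, not expected in ESC, were also shifted (-0.05, permutation p = 0.0042, adjusted p = 0.00735).

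**Figure D3:**
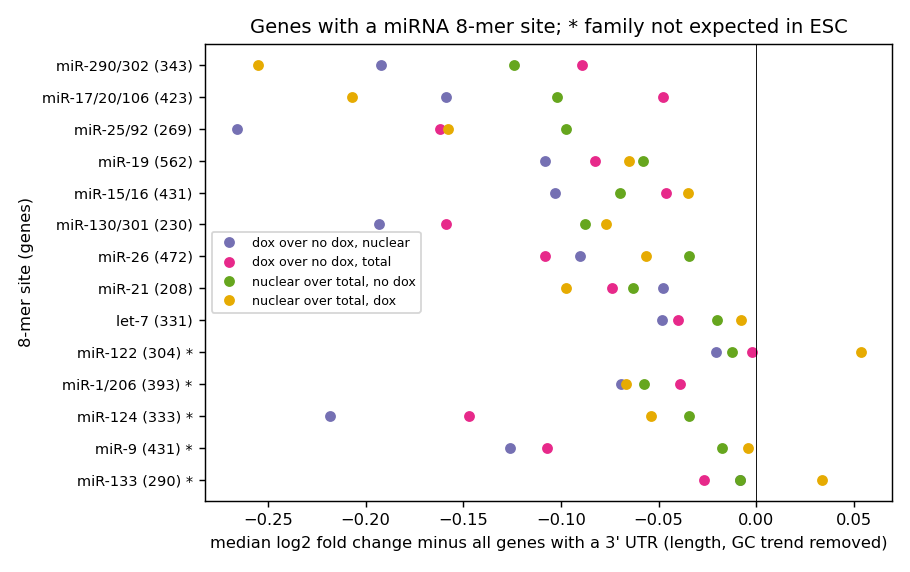
Median log2 fold change of genes with an 8-mer site of each of 14 miRNA families (number of genes in brackets) minus that of all genes with a 3' UTR, after removal of a trend on exon length and GC content, in 4 comparisons of columns. For miR-290/miR-302 it was -0.12 between nuclear and total columns without dox and -0.26 with dox, the lowest of the 14 families in both. For dox over no dox in nuclear RNA it was -0.19, above miR-25/miR-92 (-0.27) and miR-124 (-0.22), the latter not expected in ESC.

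The nuclear against total differences without and with dox shared 265 genes higher in both, where independent lists would share 23.9, and 2430 lower in both, where they would share 1232. Pearson's r across genes was 0.656 and Spearman's rho 0.677. These comparisons share no library either, but they too share the residual standard deviation of each gene.

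**Figure D4:**
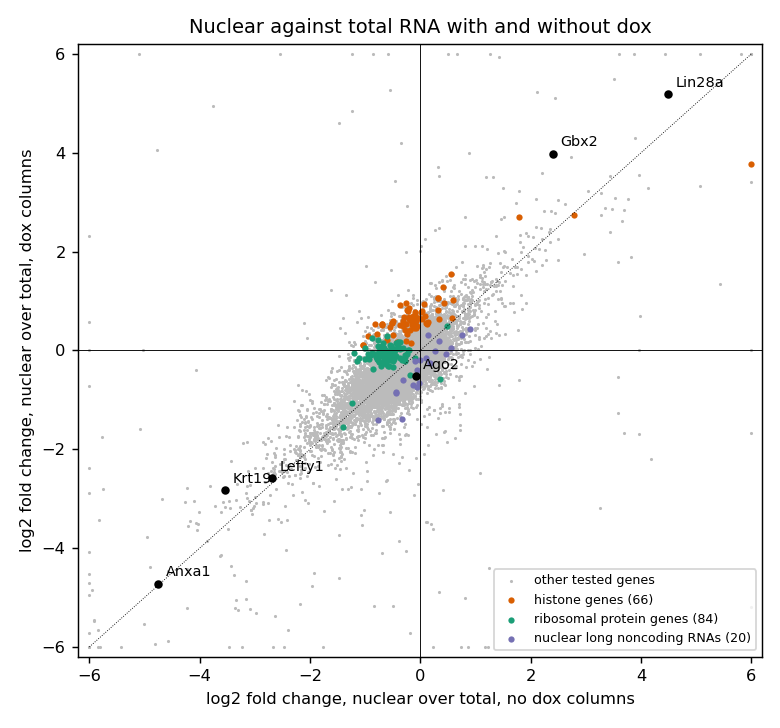
Log2 fold change of nuclear over total columns for each tested gene, without dox on the x axis and with dox on the y axis, with values beyond 6 drawn at 6. Lin28a (4.49 and 5.18) and Gbx2 lie high in both and Anxa1, Krt19 and Lefty1 low in both, while most nuclear long noncoding RNAs (20) lie near the bulk of genes.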

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

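Tests of explanations in this part were chosen only after the results were seen. As the columns are labelled, 8 gene lists and 8 sets of genes with miRNA sites had a dox effect that differed between nuclear and total RNA when the difference itself was tested (camera on the difference of effects, adjusted p below 0.05). The median differences of log2 fold changes, nuclear minus total, were 0.78 for histone genes (adjusted p = 3.3e-47), 0.54 for ribosomal protein genes (8.04e-34), 0.39 for respiratory chain genes (3.48e-15) and 0.25 for endoderm genes (0.01). They were -0.42 for nuclear-retained long noncoding RNAs (3.32e-05), -0.28 for genes with detained introns (1.66e-07), -0.24 for reported miR-290/miR-302 targets (3.12e-03) and -0.20 for snoRNA host genes (1.47e-03). All 8 lists also passed at an inter-gene correlation of 0.05. With quantile normalization the ribosomal and miR-290/miR-302 target lists no longer passed (adjusted p = 0.124 and 0.335). The endoderm list, of 5 genes, no longer passed at 5 RPKM (0.0652) or with the length (0.186) or length and GC trend removed (median -0.011, adjusted p = 0.41).

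For genes with seed sites the median differences were -0.13 for miR-290/miR-302, -0.14 for miR-17/miR-20/miR-106, -0.11 for miR-25/miR-92, -0.094 for miR-19, -0.14 for miR-130/miR-301, -0.11 for miR-26, -0.10 for miR-21 and -0.084 for miR-1/miR-206, a family not expected in ESC. At an inter-gene correlation of 0.05 none of these sets passed (smallest adjusted p = 0.338). No biological explanation was tested for these differences between fractions.

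The pattern most in need of a follow-up is the dox effect itself, in which histone, ribosomal and respiratory mRNAs rose and nuclear-retained RNAs fell in both fractions. With quantile normalization the ribosomal and respiratory lists passed in neither fraction (ribosomal adjusted p = 0.482 in nuclear and 0.821 in total RNA, respiratory 0.0586 and 0.553). The respiratory list in total RNA also no longer passed with the length trend removed (median 0.21, adjusted p = 0.198) or at 5 RPKM (0.112). It still passed with the length and GC trends both removed, so length stays open for that list. Once the trends on exon length and GC content were removed, 42.9% of tested genes were called in nuclear RNA in the same direction as before, which is 4339 of the 7073 calls before (61.3%), and among 948 genes of at least 10 RPKM in all 4 groups 84.8% were called. These values argue against a smooth trend on exon length and GC content, and against the lower depth of the dox-labelled libraries, as the whole cause. A bias that differs between genes of like length and GC content was not tested. Among 4233 genes with a 3' UTR but no site of an ESC miRNA family 72.2% were called, which argues against direct repression through such sites as the whole cause. A candidate explanation that stays open is that fraction and dox are exchanged in the column names. The nuclear-retained long noncoding RNAs lay 2.83 below the median of all genes between the dox and no-dox nuclear columns (log2 -2.83). They lay only 0.297 above it between nuclear and total columns without dox and 0.0803 with dox. In the nuclear columns 53 of 68 lincRNA genes were lower with dox and 5 higher (median -1.62). Of 59 antisense genes 43 were lower and 3 higher (median -1.49). Between nuclear and total columns these medians were -0.04 and 0.13 without dox and -0.24 and -0.02 with dox. No class was tested for enrichment. The estimated share of reads in exons also differed more with the dox label than with the fraction label. Other RNAs did not all follow the list. Rpph1, the RNase P RNA, was 19.8-fold higher with dox in the nuclear and 21.4-fold higher in the total columns. An exchange would make Rpph1 that much lower in nuclei than in whole cells. The snoRNA genes were divided. With dox 16 were higher and 2 lower in the nuclear columns, yet in total RNA 13 were lower and 5 higher with dox. A response to AGO2 or dox stays open as well.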

How the results depend on the processing

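Settings added after the data were seen were means without moderation, the authors' q-values, median-centred means, removal of the length and length and GC trends, a correlation of 0.05, and seed-site sets in the nuclear against total comparisons. No paired analysis was possible because the deposited table holds group means and no value per library. For that reason other pseudocounts, fits of only the groups compared, leaving out each library, estimated inter-gene correlations, fry and other splits of the libraries were not run, nor were count models, since the table holds no counts. Single genes kept direction and side of the threshold in 611 of 620 values under alternatives (7 weaker, 2 stronger), and single lists in 800 of 895 (62 weaker, 27 stronger, 6 reversed). Of 196 values of other results 140 stayed, and the rest follow. Unless a sentence says otherwise, the cause was not tested.

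Fewer genes pass by construction at a log2 fold change of at least 1: dox in nuclear RNA 2614 higher and 1597 lower, in total RNA 2286 and 1291, nuclear against total without dox 154 and 1150, with dox 215 and 1190. Fewer genes were also tested at 5 RPKM: nuclear RNA 900 lower, total RNA 875 lower, nuclear against total 190 higher without dox and 335 higher and 1995 lower with dox, and the difference of effects 109 higher and 12 lower. The difference of effects, 0 genes by limma as reported, gave 12 higher and 11 lower with quantile normalization, 4 and 2 with no filter, 5 higher without large-share RNAs, 6 higher with centred means, and 2 and 1 without moderation. Scalings moved the nuclear against total calls. Without dox they were 1856 higher and 1802 lower (quantile), 1157 and 1569 (centred), 1197 and 1495 (length trend removed) and 1196 and 1493 (length and GC). With dox they were 916 and 1087, 1674 and 1381, 1335 and 1380, and 1268 and 1384, in the same order.

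At a correlation of 0.05 the lists called were 9 without dox and 7 with dox between nuclear and total RNA, in place of 15 and 12, and seed-site sets called were 0 in nuclear RNA (13), 0 in total RNA (13), 0 for their difference (8) and 0 for nuclear against total with dox (5). Pearson's r of the dox effects, 0.856, became 0.806 (quantile), 0.526 (no filter), 0.939 (5 RPKM), 0.878 (without large-share RNAs), 0.839 (length) and 0.814 (length and GC). Ago2 in nuclear against total RNA with dox became log2 -0.13 (quantile), -0.15 (centred) and -0.52 without moderation (limma adjusted p = 0.064), and reversed to 0.0020 (length) and 0.0159 (length and GC); adjusted p over all alternatives ran from 0.016 to 0.995. Reversed under quantile normalization were medians or camera directions of heat shock genes with dox in nuclear RNA (-0.026), naive pluripotency genes in nuclear (-0.51, adjusted p = 9.72e-05) and total RNA (-0.19, 0.0295) and between nuclear and total without dox (0.32, 0.0488), ATF4 genes for the difference of effects (-0.22), and ribosomal genes between nuclear and total with dox (-0.081). Among other list calls that ended were, in nuclear RNA, endoderm (length trend, no filter and 5 RPKM; adjusted p = 0.524, 0.349 and 0.316) and heat shock (5 RPKM; 0.0575), in total RNA the respiratory chain (5 RPKM and length trend; 0.112 and 0.198) and immediate early genes (5 RPKM, length, length and GC; 0.583, 0.381 and 0.816), genes with detained introns in total RNA (length trend; 0.0718), and, between nuclear and total without dox, interferon-stimulated genes (5 RPKM; 0.104) and genes with detained introns (no filter and no moderation; 0.305 and 0.059). List calls gained for dox were naive pluripotency upward with no filter (adjusted p = 0.00457 in nuclear and 0.000858 in total RNA), immediate early genes in nuclear RNA and let-7 targets in total RNA with no filter (0.0359 and 0.0472) and the silencing machinery downward in nuclear RNA with quantile normalization (0.016). The other 22 gained calls lay in the difference of effects and in nuclear against total with dox. The authors' q-values below 0.05 gave 4347 higher and 2654 lower of the tested genes in nuclear RNA and 4161 and 2266 in total RNA, and over their whole set of genes 4555 and 4184, and 4334 and 3456. Depth, from 10.3 to 18.9 M reads, limits genes near 0. A group is listed at 0 only where all its libraries are. This held for 3373 genes in nuclear dox (3 libraries), 2202 in nuclear no dox (2), 3375 in total dox (2) and 1251 in total no dox (3). Whether depth accounts for these counts was not tested.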

Other observations

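Some of the annotation's gene classes among tested genes, outside the fixed lists, leaned one way between the columns labelled dox and those without; no class was tested for enrichment. Of 68 lincRNA genes 53 were lower with dox in nuclear and 47 in total RNA (medians -1.62 and -1.29), against 5 and 4 higher. Of 59 antisense genes 43 and 39 were lower (medians -1.49 and -1.31), against 3 and 3 higher. Processed pseudogenes, for which reads shared with parent mRNAs were not examined, were higher for 45 and 41 of 57 (medians 1.52 and 1.10), against 7 and 5 lower. Of 19 miRNA genes that lie within introns 9 were lower and 1 higher in nuclear RNA, and 9 were listed at 0 in nuclear RNA with dox, 2 without. In total RNA 7 were lower and 1 higher, and 9 were listed at 0 with dox, 1 without. The dox-labelled libraries were shallower, and whether depth accounts for these values at 0 was not tested. Other classes went both ways: of 34 other miRNA genes 7 were higher and 5 lower in nuclear and 5 and 3 in total RNA, and of 69 snoRNA genes 12 were higher and 14 lower in nuclear and 5 and 13 in total RNA. Between nuclear and total columns the lincRNA and antisense genes were nearer to other genes: without dox 10 lincRNA genes were higher and 7 lower (median -0.04), and 4 antisense genes higher and 2 lower (median 0.13). The snoRNA genes leaned higher in the nuclear columns, with 6 higher and 1 lower without dox (median 0.19) and 16 and 2 with dox (median 0.39). The medians of all genes were -0.31 and -0.32.

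Summed over matched genes, reads in exons came to 432600 RPM (reads scaled to the library) in nuclear RNA with dox and 276200 without, and 509600 in total RNA with dox and 362200 without. The estimated share thus differed more with the dox label than with the fraction label. By the same estimate Malat1 took 540 RPM in nuclear RNA with dox and 3261 without, and 979.6 and 4421 in total RNA.

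All tests of explanations from here on were chosen after the results were seen. Between the columns labelled nuclear and total Lin28a, Gbx2 and Lefty1 and the lists of p53 targets and interferon-stimulated genes were apart, while the naive and the primed pluripotency lists were not. If localization in the same cells were the cause, no gene should lie above RNAs that stay in the nucleus. The highest of the 20 nuclear-retained long noncoding RNAs was Firre (log2 0.90 without and 0.43 with dox). Yet 25 genes averaging at least 1 RPKM over the 4 groups, among them Lin28a, lay above every one of them by over 2 SE of the difference in both dox states. In total RNA Lin28a averaged only 0.244 RPKM without and 0.618 RPKM with dox. The bound holds only if the 20 listed RNAs mark the nucleus in these columns. Their median lay just 0.297 without and 0.0803 with dox above that of all genes. The test therefore cannot decide about localization for those 25 genes. It says nothing about the rest of the 409 genes without dox and 596 with dox that were higher in the nuclear columns. The count of such genes was made in several versions after its values were seen: 73 genes by 2 SE of the gene alone, 58 by the SE of the difference with no floor, 49 of these with at least 0.1 RPKM in all 4 groups and 6 with at least 1 RPKM there. The last falls short of the more than 10 genes asked for. A floor on each group removes genes near 0 in any group. The average was taken on the log2 scale, so a gene near 0 in some groups can fall below that floor too. Whether more than 10 genes are reached thus depends on the floor. For the genes lower in the nuclear columns localization cannot be told apart from other causes, since 5 of the 20 nuclear RNAs were lower there too with dox and a low share in nuclei has no bound in group means. Cells of another type in the total columns could raise a gene in the nuclear columns only by diluting all ESC genes alike, yet with dox 39 naive pluripotency genes had a median of -0.27 and an upper quartile of -0.01, below the lower quartile of 1.20 of the 215 genes at least 2-fold higher, which argues against such cells for the higher genes. For the genes lower in the nuclear columns a small share of other cells stays open, since it would not visibly dilute ESC genes: 80% of 20 tested markers of other cells (16, with 2 higher) were lower with dox. Those markers cannot be told apart from a change of the same cells, since group means give no value per cell or library. Genes with a miR-290/miR-302 8-mer site lay below those of the 5 families not expected in ESC, after removal of the length and GC trend, by log2 -0.25 with dox (bootstrap SE 0.0435, 1000 draws, which treats genes as independent) and -0.10 without (SE 0.0282). Relative to all genes with a 3' UTR the 8-mer sets of miR-17/miR-20/miR-106 (-0.21) and miR-25/miR-92 (-0.16) were shifted in the same way with dox, against -0.26 for miR-290/miR-302, and the miR-290/miR-302 8-mer set did not pass camera at an inter-gene correlation of 0.05 (adjusted p = 0.246). The matching values for dox against no dox were -0.10 (SE 0.0518) in nuclear and -0.02 (SE 0.0623) in total RNA, so a difference between the columns labelled nuclear and total in the activity of miR-290/miR-302, not separated from that of the other families shifted alike, is a candidate explanation, as a hypothesis.

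Ago2 was lower in the columns labelled dox although dox induces it. Removing the trend on length and GC left Ago2 at log2 -1.36 in nuclear RNA (from -1.85, SE 0.166; limma adjusted p = 1.64e-05, over the alternatives 1.42e-08 to 2.83e-04). Removing the length trend alone left log2 -0.99 in nuclear (adjusted p = 1.76e-04) and -0.75 in total RNA (from -1.41; adjusted p = 1.67e-03). Ago2 thus stayed lower with a smaller fold. The SE in these tests is that between libraries, not the scatter of genes of like length about the trend. They therefore cannot decide whether such a bias is the whole cause. Of the 500 genes nearest to Ago2 in exon length (11421 to 17236 bases) 14.8% lay below it in nuclear and 21.4% in total RNA, with medians of -0.89 and -0.68. Endogenous Ago2 that moves with other long genes, while the transgene goes uncounted, therefore cannot be told apart from a fall of Ago2 itself: no read of the transgene can be separated in group means, and the annotated 3' UTR (11064 of 14031 exonic bases) could dominate the count. If fraction and dox were exchanged in the column names, a counted transgene would set Ago2 apart between columns labelled nuclear and total. There it differed by log2 -0.08 without and -0.52 with dox. Whether the transgene is counted is unknown, so Ago2 speaks neither for nor against that hypothesis (0.297 in its own test).

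Other splits of the libraries could not be run, since no value per library was used here.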
